A study of Mus musculus with 20 samples.

How the data were processed

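Fibroadipogenic progenitors, stromal cells of skeletal muscle that can form fibroblasts and adipocytes, were sorted from hindlimb muscle of male C57BL/6J mice. Per the labels' protocols, 2 M KPCY cells, a mouse pancreatic tumour line, were injected in 50 µL into the pancreas of the tumour-bearing mice (KPC), and control mice had sham surgery. The sort kept live nucleated cells that lacked CD31, CD45 and α7-integrin and carried SCA-1. RNA with an integrity number of at least 7 went into stranded mRNA libraries, which were read as pairs of 59 bases. Mice were sampled at day 14, day 21 or day 26, and each library carries its own replicate number within a group.

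The deposited values are raw counts per gene symbol, with no normalization, as the whole numbers in the tables and the labels show. The submitters' processing notes list bcl2fastq 2.20, Bowtie, STAR, DESeq2 1.36.0 and R 4.2.1 with genome build mm10, without saying which step used which tool. The program that made the counts, its use of strand and its gene annotation are not given in the sources used here. The tables for days 14 and 21 each hold 25 symbols that were turned into calendar dates before deposit, and these were kept in the fits but are never named. The tables hold 24419, 24419 and 24421 symbols, of which 24394 are shared by all 3.

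All 20 columns were matched to samples through the library codes in the labels. Total counts ran from 12.9 to 26.4 M (megacounts) per library. Within each day the KPC libraries were compared with the controls by edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr rule (a minimum count of 10 and a minimum total of 15), a robust quasi-likelihood fit and a 2-sided test. P-values were adjusted by Benjamini-Hochberg over the genes tested that day, and a gene with an adjusted p under 0.05 is called. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values beside a fold change use the scaling of that day alone, and ranges of CPM across days use a scaling over all 20 libraries. The difference in the KPC effect between days was tested as a contrast in a single fit of all 6 groups, in which each day keeps its own controls.

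Before the data were examined, 33 gene lists were fixed from textbook knowledge. Of these, 22 cover cell states and pathways and 11 hold markers of other cell types that a muscle sort could carry. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a day. An estimated correlation and fry were run as alternatives. 3 list symbols were matched through an older name in the RefSeq synonyms and 2 had no match. The genes named were also fixed by rule. At each day these are the 6 called genes with the largest rise and the 6 with the largest fall, among genes with a mean log2 CPM of at least 1, no overlap between the groups and no predicted or clone symbol. To these come up to 3 called members of each list called by camera, in its direction, the called member with the smallest p of every other list, and always Ly6a, Pdgfra, Pecam1, Ptprc and Itga7. Not every gene that the rule picks is printed. For contrasts, the 4 largest differences in each direction are named. At day 26, where no gene was called, the same rule was applied at an unadjusted p under 0.05 after the values were seen. Clock and heat-shock genes and some list members (Fos, Egr1, Jun, Socs3, Osmr, Stat3, Cebpd, Tsc22d3, Fkbp5, Zbtb16, Mt1, Mt2, Hmgcs1, Pi16, Col1a1, Fabp4, Cdh5 and Kdr) are named after their values were seen.

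Overlap of calls between days was tested with a 1-sided hypergeometric test on the genes tested at both days. The mice and the controls differ between days, so no control library is shared. Positions come from GENCODE vM21, which uses the same genome build. Of 176 named genes, 27 share exon sequence with another gene in the tables, and without a stated use of strand such reads cannot be assigned. Counts of genes with close copies, such as C4b, Saa1, Serpina3m, Hspa1a and the ribosomal protein genes, are uncertain in the same way. Where a group had no count, a fold is given as a lower bound against 3 counts over the group, which covers counting error only, since the reads carry no molecular identifiers.

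The tests were also run on simulated counts, after the first run on the data. Each gene was drawn independently, with the control mean and a spread common to both groups, both taken from the real libraries. No library that shifts many genes together was simulated, so the shares below may not hold at day 26. There edgeR called 0 genes with KPC replicate 3 and 6972 without it. The DESeq2 and limma-voom shares come from fewer runs than those of edgeR. In edgeR, 89.7% of genes changed 4-fold and 76.6% of genes changed 2-fold were recovered among 13344 genes at day 14. At day 21 the shares were 81.6% and 62.0% among 13154 genes, and at day 26 they were 71.6% and 23.5% among 13157 genes. Of the simulated calls, 6.39%, 4.64% and 3.45% were false at the 3 days, against 9.04%, 18.1% and 29.7% with DESeq2 and 5.20%, 6.08% and 5.21% with limma-voom. At day 26 limma-voom recovered 67% of genes changed 4-fold and 24% of genes changed 2-fold among 13157 genes.

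Alternatives fixed at the same early stage as the lists were DESeq2 size factors, library size alone, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, all 20 libraries in the fit, the replicate number as a block, an absolute log2 fold change of at least 1, each library left out in turn, and at day 26 only the libraries whose code starts with the number found in both groups. An endothelial score as a covariate and a fit without robust shrinkage were added after the data were seen.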

Results

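Messenger RNA of fibroadipogenic progenitors from mouse hindlimb muscle was sequenced after KPC tumour cells or sham surgery. There were 3 control and 4 KPC libraries at day 14, 3 and 3 at day 21, and 4 and 3 at day 26. Total counts, in megacounts (M), averaged 18.0 M in the controls and 19.6 M in KPC at day 14, 24.6 and 18.5 M at day 21, and 21.4 and 18.3 M at day 26. The sort markers were present in all groups. Ly6a, which encodes SCA-1, lay at 1012.86 ± 105 CPM in controls (SD, n = 3) and 909.69 ± 77.9 CPM in KPC (SD, n = 4) at day 14, and Pdgfra, the usual progenitor marker, had its lowest group mean, 1302.54 ± 84.8 CPM, in day 14 controls. Neither gene was called at any day in all libraries of that day. At day 26 Ly6a lay at 586.50, 526 and 1204 CPM in KPC replicates 1 to 3 and at 1028 to 1460.18 CPM in controls. Without KPC replicate 3 it was lower in KPC (log2 -1.11, adjusted p 0.0017). That fit leaves out the KPC library with the highest Ly6a, so it selects on the outcome.

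The first principal component over the 20 libraries carried 34.4% of the variance. All 10 controls lay between -35.8 and -13.7 on it. The KPC libraries lay between -16.6 and -7.46 at day 14 and between 18.8 and 51.4 at day 21. At day 26, KPC replicates 1 and 2 lay at 127 and 106, and KPC replicate 3 at -8.72.

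**Figure D1:**
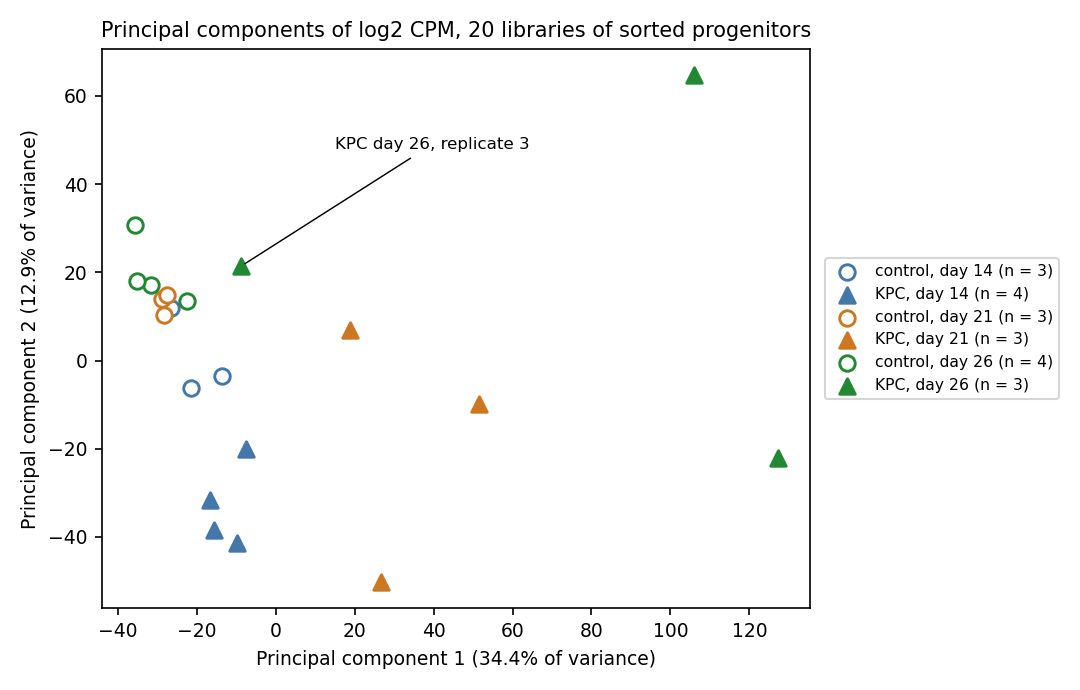
Principal components 1 (34.4% of variance) and 2 (12.9%) of log2 CPM, with 1 point per library, open circles for controls and filled triangles for KPC, coloured by day. KPC day 26 replicate 3 lies at -8.72 on component 1, and the other KPC libraries of that day lie above 100.

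The comparison at day 14 asks which progenitor transcripts differ early after tumour cell injection, in a series on pancreatic cancer cachexia. The endothelial genes Cldn5 and Egfl7, the collagen gene Col16a1 and the myelin and lipid raft genes Mal and Mall rose, and the chemokine genes Ccl2, Ccl7 and Cxcl13 fell. Col16a1 (chromosome 4, 130047840 to 130099283, mm10), which encodes a fibril-associated collagen chain, went from 26.5 ± 2.61 CPM (SD, n = 3) to 150.05 ± 30.2 CPM (SD, n = 4), a log2 fold change of 2.51 ± 0.16 (SE) with an adjusted p of 3.0e-06. Controls of other days spanned 29.7 to 142 CPM (day 21) and 127 to 252 CPM (day 26) for Col16a1. Ccl2, a monocyte chemoattractant, fell from 60.5 ± 14.99 to 17.3 ± 3.65 CPM (log2 -1.80 ± 0.19, adjusted p 0.0020), and Cxcl13, a B cell chemokine, fell from 77.9 ± 3.37 to 34.1 ± 5.42 CPM (log2 -1.19 ± 0.12, adjusted p 0.0011).

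In edgeR, 149 of 13344 genes were called at day 14, 91 higher and 58 lower in KPC, and 1781 (13.3%) did not overlap between the groups, against 5.71% by chance. Among the genes with the largest rises were Grrp1 (log2 3.80 ± 0.47), Mal (3.16 ± 0.58), Selp, which encodes the adhesion receptor P-selectin (2.79 ± 0.46), Mall (2.58 ± 0.54) and Cldn5, a tight junction gene of endothelium (2.44 ± 0.39). Grrp1, Mal and Mall stayed at or below 5.90 CPM in both group means. The largest falls outside the chemokines were in Fam71a, at most 4.74 CPM (log2 -3.06 ± 0.45), Dlg2 (-1.53 ± 0.34), the clock output gene Dbp (-1.44 ± 0.19), whose exons overlap Sphk2 on the other strand, and Plac8 (-1.28 ± 0.20). Of 12 tested endothelial markers, 2 rose, Cldn5 and Egfl7 (1.87 ± 0.26, overlapping Agpat2), and 11 were higher when adjusted over the list alone. Their median log2 fold change was 1.65 and camera gave an adjusted p of 1.0e-11, and 0.2825 with an estimated correlation between genes. Pecam1, which encodes the CD31 used to exclude endothelium, was not called (log2 1.77 ± 0.39, adjusted p 0.100, 16.8 to 57.7 CPM), nor was Ptprc, which encodes CD45 (2.22 ± 0.78, adjusted p 0.209, 2.87 CPM in KPC). Itga7, the gene of the α7-integrin that the sort excludes, rose from 2.70 to 8.86 CPM (log2 1.71 ± 0.34, adjusted p 0.0327).

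Other lists of other cell types also had positive medians at day 14. These were glial (1.20, 1 of 8 genes rose, 7 when adjusted over the list alone), mural (0.92, Notch3 alone of 10 rose, 5 over the list alone), satellite cell (0.97, 1 of 5 rose), myofibre (1.16, 0 of 15), tenocyte (0.96, 0 of 8) and macrophage markers (1.10, 0 of 14). None of these lists was called with an estimated correlation. The lists of progenitor programs called at the preset correlation alone were cholesterol synthesis (median -0.76, 0 of 17 genes called and 13 lower when adjusted over the list alone), the Dpp4/Pi16-type progenitor state (-0.29, Dpp4 alone of 15 fell and 7 were lower over the list alone), the Cxcl14/Smoc2-type state (0.36, 0 of 14 called and 10 higher over the list alone) and the glucocorticoid response (-0.61, 0 of 19). Dpp4, a marker of an early mesenchymal progenitor state, went from 490 ± 48.7 to 330 ± 22.4 CPM (log2 -0.57 ± 0.11, adjusted p 0.0299). Of the chemokine list, Ccl2, Cxcl13 and Ccl7 (-1.35 ± 0.21) fell, 3 of 23, and the list was not called (adjusted p 0.0876). Called members of lists not called included Hic1 (0.63 ± 0.12), a quiescence regulator of muscle progenitors, Ifi27l2a (-0.93 ± 0.18) and Hk2 (-1.24 ± 0.15), which encodes a hexokinase. The fibrillar and matrix list was not called either (median 0.10, adjusted p 0.0743, 2 of 28 rose).

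Camera called 11 of 30 lists at day 14. With an estimated correlation 0 lists were called (smallest adjusted p 0.2825), and 9 of the 35 splits of the 7 libraries called as many lists. DESeq2 called 563 genes at day 14 and limma-voom 649, a fit of all 20 libraries called 2 (Plac8 and Fem1a), and the endothelial covariate left 2 (Col16a1 and Ccl2). The count was 40 without control replicate 3, 41, 62 and 92 without KPC replicates 2, 1 and 3, and 255 without KPC replicate 4, and the leading number of the library codes in the labels separates KPC from control fully, so that a batch behind that number could not be told apart from the tumour.

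The comparison at day 21 asks the same question later and in other mice. Inflammatory and acute phase genes rose and cholesterol synthesis and collagen genes fell. Ptx3 (chromosome 3, 66219910 to 66225805, mm10), which encodes a secreted pattern recognition protein, went from 9.07 ± 1.31 CPM (SD, n = 3) in controls to 160 ± 14.2 CPM (SD, n = 3) in KPC, a log2 fold change of 4.14 ± 0.14 (SE) with an adjusted p of 2.9e-08. Il6 (chromosome 5, 30013114 to 30019981), the cytokine that activates STAT3, went from 2.33 ± 0.75 to 38.2 ± 2.22 CPM (log2 4.04 ± 0.23, adjusted p 3.0e-06). Sqle (chromosome 15, 59315077 to 59331192), a rate-limiting enzyme of cholesterol synthesis, fell from 57.3 ± 14.3 to 8.33 ± 1.72 CPM (log2 -2.78 ± 0.22, adjusted p 3.4e-05). Both inflammatory genes were low in the controls of this day. Il6 spanned 1.497 to 2.93 CPM in them against 28.4 to 46.0 CPM in day 14 controls and 12.8 to 40.0 CPM in day 26 controls, and Ptx3 spanned 7.68 to 10.2 CPM against 136 to 149 and 52.6 to 150 CPM.

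In edgeR, 1643 of 13154 genes were called at day 21, 839 higher and 804 lower in KPC, and 4369 (33.2%) did not overlap between the groups, against 10% by chance. Of 22 tested genes of the IL-6/STAT3 and acute phase list, 20 rose and 0 fell (median 1.69, camera adjusted p 5.3e-17, and 0.1200 with an estimated correlation between genes). No list of this day was called with the estimated correlation, and its adjusted p is marked as estimated below. Beside Il6 these included the acute phase genes Lcn2 (3.47 ± 0.37) and Serpina3m (3.64 ± 0.59), the feedback inhibitor Socs3 (1.98 ± 0.15), the receptor gene Osmr (1.89 ± 0.17) and Stat3 itself (0.85 ± 0.15). Of 23 chemokine and cytokine genes 10 rose and 1 fell (median 0.84, adjusted p 6.2e-05, 0.1479 estimated), with Cxcl13 at 3.03 ± 0.38 and Ccl7 at 2.00 ± 0.18. The mean log2 CPM of this list was 3.71 to 4.29 in KPC and 2.92 to 3.14 in the controls of this day. In day 14 controls it was 3.69 to 3.95 and in day 26 controls 3.58 to 4.07, so the KPC values did not clear those controls. Ccl7 was low in the controls of this day (7.75 to 10.9 CPM), and its KPC values (32.7 to 41.6 CPM) did not exceed the controls of day 14 (36.9 to 57.0 CPM) or day 26 (35.3 to 67.8 CPM). Il1b, at 3.02 CPM in KPC, also rose (4.71 ± 1.08). Of 18 complement genes 9 rose and 1 fell (median 0.79, adjusted p 3.9e-07, 0.1479 estimated), led by C4b (510 ± 82.9 to 2764 ± 800.25 CPM, log2 2.44 ± 0.21) and C2 (1.54 ± 0.14). Cfd, an adipocyte-enriched complement gene, had 0 counts in the controls and 211 in KPC, at least 90.1-fold higher against 3 counts over the group. That bound does not hold against the day 14 controls, which had 62 counts (day 14 KPC 167, day 26 controls 2). Of 19 glucocorticoid response genes 12 rose (median 1.32, adjusted p 3.1e-09, 0.1479 estimated), among them Mt2 (1.84 ± 0.14), Angptl4 (3.01 ± 0.60) and Pdk4 (2.47 ± 0.36). Angptl4 and Pdk4 are also fasting and PPAR target genes.

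Of 24 immediate-early and dissociation stress genes 16 rose and 2 fell at day 21 (median 0.66, adjusted p 2.0e-09, 0.1200 estimated). The risers included Ier3 (2.60 ± 0.14), Zfp36 (1.98 ± 0.13), Myc (1.85 ± 0.10), Fos (1.56 ± 0.11) and Egr1 (1.04 ± 0.14), and the heat-shock gene Hspa1a fell (-0.91 ± 0.17). Of 20 adipogenic and lipid genes 11 rose and 2 fell (median 1.08, adjusted p 1.6e-06, 0.1479 estimated), with Plin4, a lipid droplet coat gene, at 3.86 ± 0.30, Car3 at 3.16 ± 0.37 and the fatty acid carrier Fabp4 at 2.56 ± 0.29. In the Cxcl14/Smoc2-type state 6 of 14 genes rose and 1 fell (median 0.30, adjusted p 0.0363, 0.4677 estimated), among them the lipid-binding Apod (771 ± 75.4 to 4175 ± 1425 CPM, 2.44 ± 0.24), Lpl (1.04 ± 0.14) and Cxcl14 (0.81 ± 0.14). Of 17 genes of the p53 and senescence list 3 rose, Btg2 (1.55 ± 0.15), Cdkn1a (1.16 ± 0.14) and Plk2 (0.90 ± 0.17), and 1 fell (adjusted p 0.0363, 0.2617 estimated). Of 28 cytosolic ribosomal protein genes 2 rose (Rps4x and Rpl23) and 14 were higher when adjusted over the list alone (median 0.27, adjusted p 7.2e-06, 0.5475 estimated), and of 28 oxidative phosphorylation genes 0 were called (median -0.17, adjusted p 0.0202, 0.5526 estimated).

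All 16 tested cholesterol synthesis genes fell (median -2.01, adjusted p 1.5e-12, and 0.2617 with an estimated correlation), with Hmgcs1 at -2.15 ± 0.32. Of 28 fibrillar and matrix genes 18 fell and 4 rose (median -0.98, adjusted p 5.1e-06, 0.3056 estimated). Col3a1 went from 23211 ± 3032 to 6837 ± 3146 CPM (-1.76 ± 0.31), Col6a2 changed by -1.66 ± 0.22, Col5a1 by -1.55 ± 0.24 and Fbn1 by -1.48 ± 0.17. Of 15 genes of the Dpp4/Pi16-type state 10 fell (median -1.07, adjusted p 3.8e-09, 0.2617 estimated), among them Pi16 (3807 ± 331 to 1581 ± 342 CPM, -1.27 ± 0.16), Cd248 (-1.64 ± 0.24) and Dact2 (-1.92 ± 0.28), and Dpp4 itself was not called (-0.12 ± 0.12). Of 16 progenitor identity genes 3 rose and 4 fell (adjusted p 0.7349), and Cd34 fell by 1.14 ± 0.15 on the log2 scale. Other called genes with large changes were Chchd10 (5.22 ± 1.02, overlapping Mmp11), Tmem252 (4.68 ± 0.42), Selp (4.44 ± 0.46), Lrg1 (4.33 ± 0.73) and Csf2rb (4.23 ± 0.53), all higher, and Fam78a (-3.46 ± 0.60, overlapping Nup214), Rnf112 (-3.25 ± 0.75), Flrt1 (-3.09 ± 0.77) and Syt13 (-2.91 ± 0.44), all lower. The control means of these genes were 12.6 CPM or less.

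Endothelial, macrophage and myofibre markers were called as lists at day 21. Of 12 endothelial markers 7 rose (median 1.89, adjusted p 5.1e-06, and 0.4677 with an estimated correlation), including Vwf (2.52 ± 0.54), Cldn5 (2.39 ± 0.22) and Pecam1 (18.0 ± 2.56 to 88.2 ± 52.5 CPM, 2.30 ± 0.51, adjusted p 0.0463). The mean log2 CPM of this list was 5.93, 5.12 and 4.29 in KPC replicates 1 to 3 and 3.45 to 3.56 in controls. Of 10 splits of the libraries, the real one included, 3 gave this list a camera p as small. Macrophage markers had a median of 1.20 (adjusted p 0.0055, 0.5475 estimated, with Cd14 alone of 13 rising) and myofibre markers a median of 2.59 (adjusted p 0.0012, 0.5475 estimated, 0 of 15 called). KPC replicate 1 was highest for both, with Acta1 at 132, 23.8 and 12.8 CPM in KPC replicates 1 to 3. With the quality weights of limma-voom the medians were 0.47 and 0.9985, and without KPC replicate 1 the macrophage and monocyte markers were not called (adjusted p 0.1802). Tenocyte (median 0.07, adjusted p 0.4487), glial (0.97, adjusted p 0.1767) and epithelial markers (-0.15, adjusted p 0.7349) were not called. Mural markers were mixed, with 2 of 9 higher and Cspg4 lower (-1.79 ± 0.33), and were not called as a list (adjusted p 0.2248). Ptprc (2.80 ± 1.31, adjusted p 0.1996) and Itga7 (0.70 ± 0.47, adjusted p 0.3749) were not called. For lists not called or not tested, the called members with the smallest p included Has1 (1.69 ± 0.15), Iigp1 (1.21 ± 0.17) and Pfkfb3 (2.06 ± 0.23). Others were Atf3 (1.46 ± 0.13), Gabarapl1 (0.75 ± 0.13), Mcm7 (0.94 ± 0.19), Cdh19 (1.4995 ± 0.40) and Alas2 (2.72 ± 0.54). Igfbp5 (-1.35 ± 0.15) and Cnn2 (-1.06 ± 0.18) fell. Further members were called, with 6 rising and 10 falling in matrix processing, the list of Has1. In the unfolded protein and integrated stress response list, which holds Atf3, 2 rose and 5 fell. The counts were 4 and 1 for interferon response, 4 and 2 for hypoxia and glycolysis, and 6 and 4 for secreted factors.

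Camera called 16 of 29 lists at day 21, fry called 12, and with an estimated correlation 0 were called (smallest adjusted p 0.1200), while 2 of the 10 splits of the 6 libraries called as many. With library size alone 1671 genes were called at a split of 1058 higher and 613 lower. The count was 717, 766 and 853 without control replicates 1, 2 and 3, 2644 without KPC replicate 1, 436 in the fit of all 20 libraries and 358 with the endothelial covariate. The library code number separates the groups fully at this day too, so a batch behind it could not be told apart from the tumour.

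**Figure D2:**
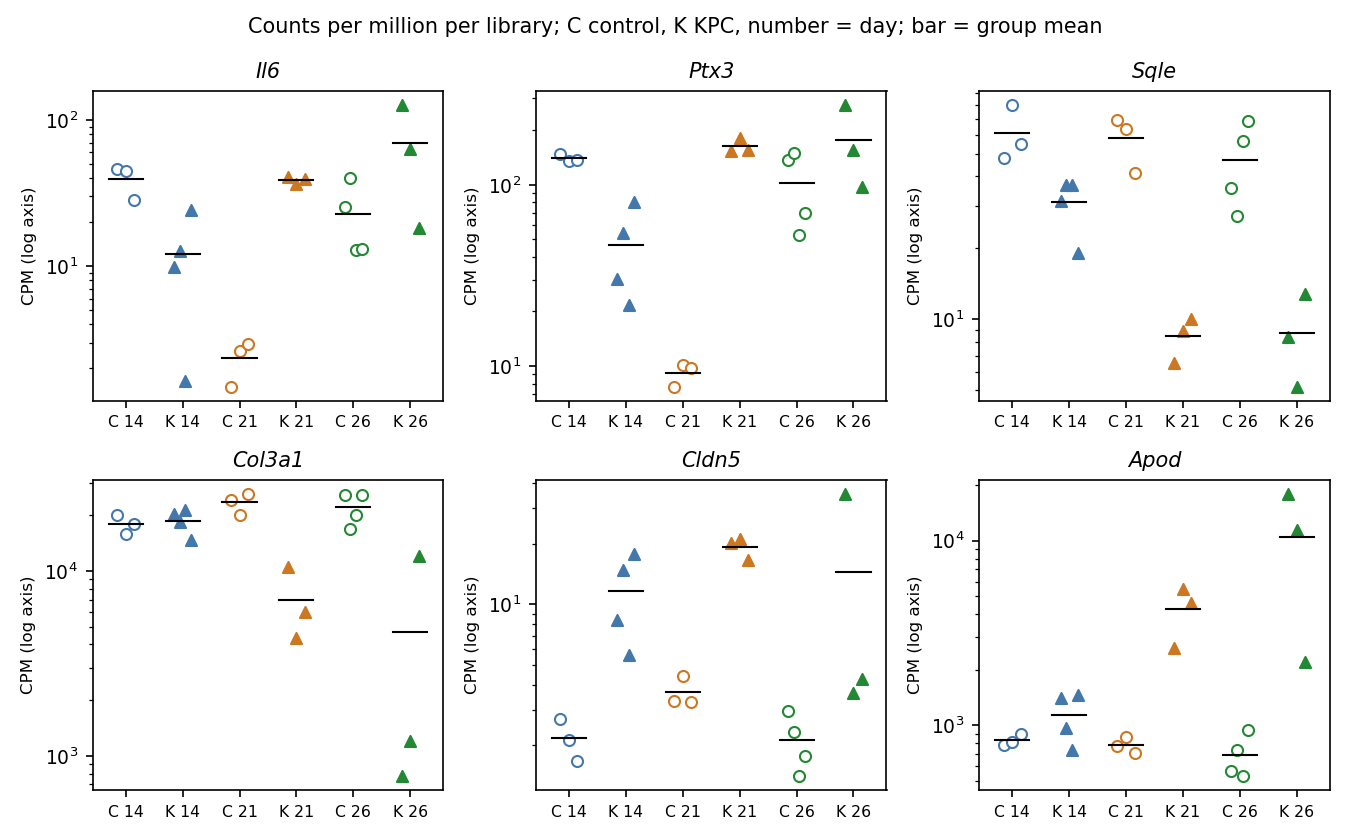
CPM of Il6, Ptx3, Sqle, Col3a1, Cldn5 and Apod in each library on a log axis, with open circles for controls (C), triangles for KPC (K), the day as a number and a bar at each group mean. The day 21 controls have the lowest Il6 (1.497 to 2.93 CPM) and Ptx3 (7.68 to 10.2 CPM) among the control groups.

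At day 26 edgeR called no single gene in the full set of 7 libraries, while DESeq2 called 2757 and limma-voom 4519, and 12 of 29 lists were called by camera at its preset correlation. With an estimated correlation no list was called (each of the 12 had an adjusted p of 0.6136), and 23 of the 35 splits of the libraries called as many lists. The IL-6/STAT3 and acute phase list had a median log2 fold change of 1.80 (camera adjusted p 8.4e-09, 20 of 23 genes higher when adjusted over the list alone) and the glucocorticoid response list one of 1.80 (adjusted p 3.2e-08, 16 of 19 higher and 1 lower over the list alone). Cholesterol synthesis had a median of -1.46 (adjusted p 4.2e-08, 14 of 17 lower over the list alone), the Dpp4/Pi16-type state one of -1.59 (adjusted p 1.4e-06, 6 of 15 lower over the list alone) and the fibrillar and matrix list one of -1.39 (adjusted p 1.7e-04, 2 of 28 higher and 0 lower over the list alone). Of the lists called at day 21, complement (adjusted p 0.2322), chemokines and cytokines (0.6007), the Cxcl14/Smoc2-type state (0.1025), p53 and senescence (0.1071) and oxidative phosphorylation (0.1025) were not called at day 26. Endothelial (2.43, adjusted p 0.0394), macrophage (2.97, adjusted p 0.0169) and myofibre markers (1.26, adjusted p 0.0017) were called. KPC replicate 1 carried the first 2 of these, with Pecam1 at 242, 27.6 and 12.6 CPM and Cd14 at 111, 10.01 and 6.06 CPM in KPC replicates 1 to 3. Without it the endothelial markers (adjusted p 0.2791) and the macrophage and monocyte markers (adjusted p 0.5624) were not called.

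EdgeR called 0 of 13157 genes at day 26. The smallest adjusted p was 0.0592, shared by 212 genes, and 4508 genes had an unadjusted p under 0.05, 2674 with positive and 1834 with negative log2 fold changes. Between the groups, 3811 genes (29.0%) did not overlap, against 5.71% by chance. DESeq2 called 2757 genes (1796 higher, 961 lower) and limma-voom with quality weights 4519 (2329 higher, 2190 lower). The values that follow were therefore chosen on unadjusted p after the fact, and their adjusted p lay between 0.0592 and 0.1378. Igfbp3 (chromosome 11, 7206086 to 7213923, mm10), which encodes a binding protein of insulin-like growth factors, stood at 125 ± 50.1 CPM in controls (SD, n = 4) and 6968 ± 5947 CPM in KPC (SD, n = 3), a log2 fold change of 5.80 ± 1.11. Apod stood at 680.02 ± 179 and 10322 ± 7867 CPM (3.92 ± 0.65). Glucocorticoid-responsive genes had values of 3.63 ± 0.55 (Klf15), 3.14 ± 0.46 (Zbtb16), 3.33 ± 0.63 (Pdk4), 1.95 ± 0.35 (Fkbp5) and 1.76 ± 0.24 (Tsc22d3). Stat3 had 1.69 ± 0.30 and Osmr 1.85 ± 0.20. The adhesion genes Selp (6.82 ± 1.29) and Sele (5.72 ± 1.14) and the autophagy gene Ulk1 (1.62 ± 0.34) had positive values. Selp stood at 224, 16.9 and 7.18 CPM and Sele at 79.4, 7.24 and 2.93 CPM in KPC replicates 1 to 3, and without replicate 1 their values were 3.98 and 3.13. Negative values were found for Sqle (-2.41 ± 0.42), Msmo1 (-2.25 ± 0.37), the proliferation genes Mki67 (-3.05 ± 0.66) and Top2a (-3.11 ± 0.98), and the matrix genes Col3a1 (-2.23 ± 0.94), Sparc (-1.94 ± 0.57), Loxl2 (-1.89 ± 0.58) and Serpinh1 (-1.66 ± 0.57). The fibrillar and matrix list had a mean log2 CPM of 8.37, 8.71 and 9.87 in KPC replicates 1 to 3 and 10.05 to 10.48 in controls. KPC replicates 1 and 2 thus carried most of that fall. The cell cycle list as a whole was not called (adjusted p 0.1374, 2 of 28 higher and 3 lower over the list alone), and its member Mcm7 had a positive value (2.04 ± 0.46). Controls were highest for this list at day 26 (mean log2 CPM 1.39 to 2.37, against 0.91 to 1.27 at day 14 and 0.98 to 1.13 at day 21). Day 26 KPC replicates 1 to 3 stood at 1.68, 1.13 and 0.46.

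KPC replicate 3 lay nearest the controls at day 26, and the count of calls depends on it, on the tool and on the libraries in the fit. Without it edgeR called 6972 genes with 2 KPC libraries against 4 controls, and with it a fit of all 20 libraries called 4889. Dropping the KPC library nearest the controls selects on the outcome, so apart from the sort marker Ly6a no gene or list is read from the smaller fit here.

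The remaining lists called by camera at day 26 were the immediate-early list (median 0.59, adjusted p 1.6e-04), ribosomal proteins (0.33, adjusted p 2.4e-04), adipogenic and lipid genes (1.18, adjusted p 0.0025) and matrix processing (-0.36, adjusted p 0.0215). KPC replicate 1 stood highest for adipogenic and lipid genes (mean log2 CPM 5.86, 4.65 and 3.34 in KPC replicates 1 to 3, controls 2.84 to 3.12), and Adipoq stood at 40.6, 0.471 and 0 CPM. Fry called 2 lists (IL-6/STAT3 and glucocorticoid response). Leaving out any other single library gave 0 genes, and the 5 libraries that share a code number, which excludes KPC replicate 3 and control replicate 4, gave 6287.

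**Figure D3:**
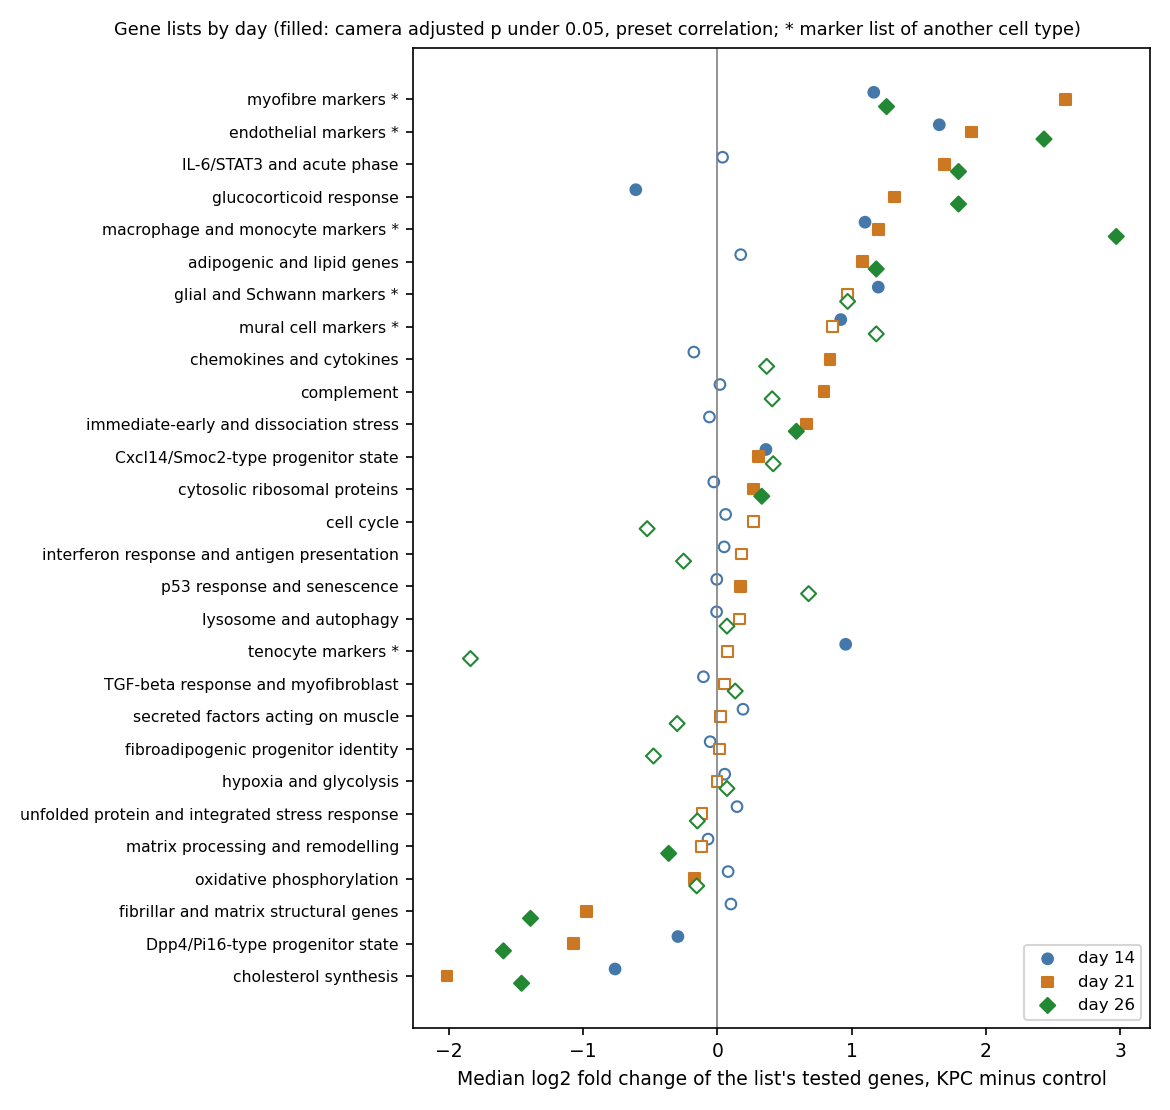
Median log2 fold change, KPC minus control, over the tested genes of each list that was tested at all 3 days (circles day 14, squares day 21, diamonds day 26; filled where camera with the preset correlation gave an adjusted p under 0.05). Cholesterol synthesis lies at -0.76, -2.01 and -1.46 and endothelial markers at 1.65, 1.89 and 2.43, and the near-zero hypoxia and glycolysis median at day 21 changes sign with the scaling.

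The contrasts between days ask whether the KPC effect itself differed. The library code number separates KPC from control fully at days 14 and 21. A batch behind it could enter every contrast and could not be told apart from the tumour. From day 14 to day 21 the effect changed for 91 of 14141 genes, more positive in 76 and more negative in 15. Among the called and named genes with more than 3 counts in each group, the largest differences were in Ptx3 (5.74 ± 0.66 on the log2 scale, adjusted p 9.3e-04) and Il6 (5.73, adjusted p 0.0142), whose values at day 14 were -1.57 ± 0.45 (adjusted p 0.2056) and -1.67 ± 0.71 (adjusted p 0.3728). For Ptx3 and Il6 the day 21 controls were the lowest control group, so low controls contribute to these differences. Next were Cish (5.32), a STAT5 target, and Pla2g2d (4.39). Ccl7 (3.37, adjusted p 0.0319) and Cxcl13 (4.24, adjusted p 0.0268) were lower in KPC at day 14 and higher at day 21, each against the controls of its own day, and the day 21 controls were the lowest for both genes. Differences were negative for Fam78a (-4.22), Rcor2 (-2.62), Smtnl2 (-2.10) and Nif3l1 (-1.4981). Lists with a large shift were IL-6/STAT3 (camera adjusted p 1.3e-14), glucocorticoid response (3.4e-10), both more positive, and cholesterol synthesis (1.1e-06), more negative, and each was lost with an estimated correlation (adjusted p 0.1166, 0.1166 and 0.4946).

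From day 14 to day 26 the effect changed for 2024 genes, 1357 more positive and 667 more negative. The acute phase gene Saa1 (6.53, adjusted p 0.0262) and the cysteine dioxygenase gene Cdo1 (6.03, adjusted p 0.0143) had the largest positive differences among the called and named genes with more than 3 counts in each group, and Chad (-4.63), Adgra1 (-4.61), Spon2 (-4.60) and Wif1 (-4.53) the largest negative ones. Saa1 stood at 109, 8.54 and 1.06 CPM in day 26 KPC replicates 1 to 3 (controls 0.149 to 1.11 CPM), and Cdo1 at 172, 84.2 and 2.53 CPM (controls 1.64 to 2.48 CPM). Col16a1 differed by -3.41 (adjusted p 0.0149). From day 21 to day 26 edgeR called 0 genes (smallest adjusted p 0.0787, 1825 at an unadjusted p under 0.05, 56 in DESeq2). The count for days 21 against 14 was 388 in DESeq2, 1130 with only the 4 groups concerned, and 24 to 162 with a library left out, lowest without control day 21 replicate 2 and highest without KPC day 21 replicate 1. For days 26 against 14 it was 466 without KPC day 26 replicate 2 and 5900 without KPC day 26 replicate 3, and for days 26 against 21 it was 3201 without the latter. Other single libraries also moved the first 2 counts more than 1.5-fold (day 21 against 14: 29 without control day 21 replicate 1, 36 without KPC day 21 replicate 2, 50 without KPC day 21 replicate 3, 54 without control day 21 replicate 3, 37 without control day 14 replicate 1 or 3, 44 without KPC day 14 replicate 1, 2 or 3; day 26 against 14: 753 and 1047 without control day 14 replicates 1 and 3, 1234 without replicate 2, 1072 and 1092 without KPC day 14 replicates 1 and 2, 1114, 1285 and 1156 without control day 26 replicates 1, 3 and 4, 1059 without KPC day 26 replicate 1).

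Calls of days 14 and 21 overlapped. Of 12974 genes tested at both, 35 were higher at both, against 5.81 for independent lists (hypergeometric adjusted p 9.2e-19), and 8 were lower at both, against 3.52 (adjusted p 0.0231). A further 10 genes were called lower at day 14 and higher at day 21. Genes vary together, so the hypergeometric p-values are too small by an unknown amount and do not measure spread between mice. The endothelial covariate left 2 genes called at day 14, so a shared endothelial signal behind the overlap is not excluded. Of the 821 genes called higher at day 21 and tested at day 26, 780 (95.01%) had a positive log2 fold change there, and of 801 called lower 779 (97.3%) had a negative one, against 74.0% of all 12856 genes with the same sign at both days. Across genes, which are not independent replicates, log2 fold changes of days 21 and 26 had r = 0.698 and rho = 0.644, and those of days 14 and 21 had r = 0.224 and rho = -0.0014.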

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

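All tests of technical explanations in this part were chosen after the results were seen, while the outlier test and the contrasts between days were planned. The outlier test took each named gene and list in the groups of 4 libraries. It marked 11 of 98 groups of 4 values, against 4.90 by chance at 1 in 20. In KPC at day 14, replicate 4 was low for Mall (1.4974 CPM, the others 3.71 to 3.89), matrix processing (mean log2 CPM 7.19), satellite cell markers (1.30), mural markers (3.83) and erythroid markers (-0.98). Replicate 3 was low for Ccl7 (12.4 CPM, the others 22.2 to 22.6) and ribosomal proteins (7.70) and high for myofibre markers (3.72), and replicate 2 was high for endothelial markers (5.44). In day 26 controls, replicate 3 was low for secreted factors acting on muscle (5.25) and replicate 2 high for myofibre markers (2.34).

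The effect of KPC at day 21 differed from that at day 14 for 91 genes, by a test of the difference. A batch behind the library code number, which separates the groups fully at both days, could give part of such differences. Among the named genes the log2 difference was positive for Ptx3 (5.74), Il6 (5.73), Cish (5.32), Pla2g2d (4.39), Plin4 (4.27), Cxcl13 (4.24), Angptl4 (3.83), Ccl7 (3.37), Has1 (3.20), C4b (3.08), Myc (2.56), Plac8 (1.82) and C2 (1.57). The day 21 controls were the lowest control group for Ptx3, Il6, Cxcl13 and Ccl7. Angptl4 also lay low in them (12.1 to 40.7 CPM), against 31.5 to 79.7 CPM in day 14 controls and 44.4 to 86.6 CPM in day 26 controls. The log2 difference was negative for Nif3l1 (-1.4981), Smtnl2 (-2.10), Rcor2 (-2.62) and Fam78a (-4.22). Nif3l1 shares exon sequence with Ppil3 and Orc2.

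The effect at day 26 differed from that at day 14 for 2024 genes. Acute phase and cytokine genes among them were Saa1 (6.53), Serpina3m (3.55), Lcn2 (3.36), Il6 (3.30), Ptx3 (2.37), Cxcl13 (4.10), Ccl2 (2.70), Ccl7 (2.44), C4b (2.45) and the cytokine signalling inhibitor Cish (5.93). Ccl2, Ccl7 and Cxcl13 fell at day 14, and Ptx3 and Il6 had negative values there that were not called. Part of these 5 differences thus comes from day 14, and edgeR called 0 genes within day 26. Metabolic genes were Cdo1 (6.03), Plin4 (4.37), Pdk4 (3.76), Pfkfb3 (3.73), Hk2 (2.41), Apod (3.46), Pla2g2d (4.63) and Chchd10 (5.54). Alas2 (3.08) is on the list of erythroid markers. The mean log2 CPM of that list was 3.06, 2.14 and -0.62 in day 26 KPC replicates 1 to 3 and -1.95 to -1.07 in day 26 controls. At day 14 it was -0.98 to -0.0020 in KPC and -1.25 to -0.46 in controls. Further positive differences were found for Tmem252 (4.85), Dbp (3.19), Myc (2.47), Ier3 (2.13), Mcm7 (1.93), Cdkn1a (1.90), Btg2 (1.7550) and Gabarapl1 (1.17). Negative ones were found for Nif3l1 (-1.10), Hic1 (-1.54), Col16a1 (-3.41), Wif1 (-4.53), Spon2 (-4.60), Adgra1 (-4.61) and Chad (-4.63). For 3 genes, Cfd, Cidec and Fam71a, a group had 3 counts or fewer, and their differences are left out, which was decided after the values were seen.

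Endothelial markers were higher in KPC although the sort excludes CD31. After removal of group means, their genes had a mean pairwise correlation of 0.7722 over the 20 libraries, against 0.1072 at the 95th percentile of 1000 random lists. Carried-over endothelial cells or RNA would give this, but so would any genes regulated together, so the correlation alone cannot tell these apart. Thinning every library to the smallest total of its day left medians of 1.6146 at day 14 (1.6524 before) and 1.9028 at day 21 (1.8900 before). Thinning keeps each gene's expected share of a library, so the medians could hardly move and cannot decide on unequal depth. A lower share of sorted cells would lift all other cell types alike, so list medians were compared with list labels permuted over genes. The permutation p was 0.1083 at day 14 (8 list medians from 0.27 to 1.65). At day 21 it was 1.0e-04, the smallest possible (7 medians from -0.15 to 2.59). Genes of a list vary together and the p-values do not measure spread between mice, so they cannot decide this at either day.

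KPC replicate 3 of day 26 lay near the controls. Its score over the genes called at day 21 stood 0.5204 above the highest control (SD of the controls 0.1992). Of genes called higher and lower at day 21, 61.0% and 59.2% lay beyond all 4 controls, against 20% by chance, though genes are not independent. The score was -1.42, nearer the controls (-2.42 to -1.94) than KPC replicates 1 and 2 (1.04 and 0.76). These values argue against a control like these 4 under a KPC label. A control of another batch could not be told apart, since this library alone carries its code number. Its depth, 20.1 M (megacounts), lay within 16.8 to 25.8 M of the other 6 libraries. KPC replicate 1 had 10 of 11 lists of other cell types above all controls, so other cells could explain part of its distance, while replicate 2 had 2 and replicate 3 had 3.

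IL-6/STAT3 genes at day 21 stood 0.8289 above the highest control of days 14 and 26 (mean log2 CPM, SD of those controls 0.1128), so that low day 21 controls would not give the whole rise. With the endothelial covariate the median was 1.8166 (1.6913 without it), 15 members were called (20 without it) and the median SE was 0.2980 (0.1748 without it). The endothelial score separated the groups fully at day 21, so the covariate cannot exclude carried-over endothelial cells for either list. Immediate-early genes did not clear those controls (-0.1477), and low day 21 controls could give their rise. Their covariate median was 0.8135 (0.6626 without it), with 8 members called, against 16 higher and 2 lower without it. Heat-shock genes of that list had a median of -0.1921, which leaves stress of cell preparation open.

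Swapping group labels tells how often other groupings give as many calls. At day 14, 1 of 35 groupings, the real one, gave 149 genes, and the next gave 15. At day 21, 1 of 10 did (1643, next 0), too few groupings to tell. At day 26 all 35 gave 0 called genes, while 1 of 35 reached 4508 genes at an unadjusted p under 0.05 (next 3131). For lists, 9 of 35, 2 of 10 and 23 of 35 groupings gave as many as the real one, with up to 16, 16 and 17 lists in other groupings. Among 100 groupings, 1 gave 91 genes for day 21 against 14 (next 0), 1 gave 2024 for day 26 against 14 (next 720), and all 100 gave at least 0 for day 26 against 21 (up to 396). The number of groupings was raised to 100 after a smaller run had been seen.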

How the results depend on the processing

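The endothelial covariate and the fit without robust shrinkage were added after the results were seen. At day 14 the count of 149 was 278 without a filter, 80 with the strict filter, 563 in DESeq2, 649 in limma-voom, 2 with all 20 libraries, 75 at a log2 fold change of 1, 2 with the endothelial covariate, and 40 to 255 with a library left out. At day 21 the count of 1643 was 436 with all 20 libraries, 635 at a log2 fold change of 1, 358 with the covariate, and 717 to 2644 with a library left out. At day 26 the count of 0 was 2757 in DESeq2, 4519 in limma-voom, 4889 with all 20 libraries, 6287 with the shared code number, and 0 to 6972 with a library left out. The contrast of days 21 and 14 (91) was 388 in DESeq2, 1130 with 4 groups, and 24 to 162 with a library left out. That of days 26 and 14 (2024) was 1113 with 4 groups and 466 to 5900 with a library left out. That of days 26 and 21 (0) was 56 in DESeq2, 1 with library size alone (Dbp), and 0 to 3201 with a library left out. List calls were 0 at each day with an estimated correlation, 0 and 2 with fry at days 14 and 26, and 5 with the covariate at day 14. Shared calls of days 14 and 21 were 4 higher and 2 lower at an adjusted p under 0.01, and 132 and 43 in DESeq2, which also shared 84 and 44 between days 14 and 26 and 695 and 388 between days 21 and 26.

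Replicate numbers were not treated as pairs in the main fits. Same-number libraries had correlations of -0.1148, -0.0517 and -0.1011 at day 14 and 0.0398, -0.0591 and -0.0034 at day 21. At day 26 they were 0.0690, 0.0681 and 0.1470, and not every library correlated best with its own number. With so few libraries per group, these values cannot exclude a step shared by a number. As a block the replicate numbers gave 369 genes at day 14, 1545 at day 21, 0 at day 26, and 96, 829 and 5 in the contrasts. Among the 5 were the clock genes Dbp (adjusted p 0.0215) and Tef (0.0390). With the covariate, which is built from the endothelial list, camera's direction turned, among lists called in at least 1 of the 2 fits, for endothelial markers (adjusted p 0.8292), macrophage and monocyte markers (0.6207), mural cell markers (0.4337) and myofibre markers (0.0567) at day 14, endothelial markers (0.8113), macrophage and monocyte markers (0.0166), mural cell markers (0.0074) and myofibre markers (1.015e-04) at day 21, and endothelial markers (0.9720) at day 26. The endothelial medians were then near 0 (0.0345, -0.0774 and 0.0052), and the glial median at day 21, called in neither fit, went from 0.97 to -0.90.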

Other observations

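Circadian clock genes were looked at after their values were seen, with no list fixed in advance. At day 14 the clock output genes Dbp (log2 -1.44), Nr1d2 (-1.24) and Per3 (-0.55) fell, and at day 21 Dbp fell (-1.52). At day 26 no clock gene was called, and values were positive for Ciart (3.65), Nr1d1 (2.58), Nr1d2 (2.23), Dbp (1.73), Tef (1.68), Hlf (1.65), Cry2 (1.60), Per1 (1.55), Per2 (1.46) and Per3 (1.22) and negative for Arntl (-0.95) and Npas2 (-0.82). The contrast of days 26 and 14 called Nr1d1 (3.76), Nr1d2 (3.48), Dbp (3.19), Tef (2.18) and Per3 (1.79), with adjusted p from 0.0037 to 0.0060, as well as Cry2 (1.95), Per1, Hlf, Ciart, Npas2 (-1.23) and Arntl (-1.31), and not Per2 (adjusted p 0.1131), Clock (0.4190) or Cry1 (0.4699). The controls moved as well, with Nr1d2 at 101 to 159 CPM in day 14 controls, 10.2 to 35.5 CPM in day 26 controls and 73.0 to 151 CPM in day 26 KPC. Nr1d1 lay at 104 to 223 CPM in day 14 controls and 18.7 to 61.0 CPM in day 26 controls. None was called between days 14 and 21. Between days 21 and 26 none was called in the full fit, while Dbp was called with library size alone (adjusted p 0.0435) and without control day 26 replicate 4 (0.0038), and Dbp (0.0093) and Per3 (0.0285) without KPC day 26 replicate 1. The time of day at which the muscles were taken is not given in the sources used here. Dbp shares exon sequence with Sphk2 and Nr1d1 with Thra.

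Between days 21 and 26 the interferon response list (camera adjusted p 3.5e-05), the Dpp4/Pi16-type state (0.0019), chemokines and cytokines (0.0110), progenitor identity (0.0110), the fibrillar and matrix list (0.0262), matrix processing (0.0262), tenocyte markers (0.0262) and complement (0.0356) had more negative effects at day 26, and none was called with an estimated correlation. Markers of epithelium and of the pancreatic tumour cells were not called at day 14 (median 0.27, adjusted p 0.9000) or day 21 (-0.15, adjusted p 0.7349). At day 26 too few of them passed the filter for a list test, and in DESeq2 2 of 8 were higher (median 1.0162).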
